A study of Mus musculus with 6 samples.

How the data were processed

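RNA sequencing libraries came from mouse hematopoietic cells transformed with MLL-AF9, with 3 libraries labelled A20 WT and 3 labelled A20 KO. Per the labels, RNA was converted with a stranded TruSeq mRNA kit, which selects polyadenylated RNA. The deposited values are a raw count per gene and library, without normalization. Per the submitters' processing notes, reads were checked with FastQC 0.11.7, aligned to mm10 with HISAT2 2.0.5 and counted with featureCounts 1.5.2; the annotation and the strand setting are not given in the sources used here.

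The table held 24062 genes, of which 7384 had no read in any library. The 6 libraries held 16113320 to 25415274 counted reads. A count of 3, used as the floor for a gene at 0, corresponded to 0.13, 0.17 and 0.15 CPM in the WT-labelled and 0.14, 0.13 and 0.18 CPM in the KO-labelled libraries. Folds against a group at 0 were computed against the mean of these floors, and genes with 1 to 3 counts in a group were given a 95% counting interval.

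The contrast was KO-labelled minus WT-labelled. Counts were analysed in R 4.3.3 with edgeR 4.0.16: TMM scaling, the default low-count filter, which left 12126 genes, and the robust quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Library measures were compared by exact two-sided permutation. Libraries were compared in pairs by chi-square per degree of freedom and by principal components. The tools were tested on simulated data of 12126 genes, where edgeR recovered 34% of 100 genes changed 2-fold and 85% of 100 changed 4-fold, with 4 false calls among 123; limma-voom recovered 30% and 85% (4 of 119 false) and DESeq2 59% and 94% (47 of 200 false).

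The design, the alternatives except those named as added, the rule for named genes and 30 gene lists were fixed before the data were examined. The lists held 713 symbols, of which 692 were in the table, 8 of them by an older name. Lists with at least 5 tested members, 29 in all and 8 of them primary, were tested with camera from limma 3.58.1 at a preset correlation of 0.01, in 1 Benjamini-Hochberg family, and again with an estimated correlation and with fry. Of 15 symbols listed for mitochondrially encoded genes 0 were found in the table, so these genes and their share of counts could not be analysed. The rule named Tnfaip3, the 10 genes with the largest rise and the 10 with the largest fall among called genes with a mean of at least 5 CPM and no overlap between groups, the 10 smallest p-values, up to 4 called members per list in order of p (without any, the 2 most abundant) and the sex-linked genes. Predicted gene models were counted (187 called) and not named. Beyond the rule, 21 genes were named after their values were seen.

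Gene positions came from GENCODE annotation of the same mouse assembly, where 22708 symbols (94.4%) had a single position. The share of a gene's 31-mers found in transcripts of other genes, sampled at 1 in 4, was computed in Python 3.11.15. Genes with at least 20% are called multi-copy here. The share was taken over both strands, so it also counts genes that overlap another gene's transcripts and does not mark gene copies alone.

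Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, non-robust dispersion, a block, stricter thresholds, removal of sex-linked and Tnfaip3-linked genes, and leaving out each library. Added after the data were seen were a term for replicate 1, replicates 2 and 3 alone, summed replicates, and removal of Rn45s or of multi-copy genes. Exon-level reads were not used here.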

Results

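Gene expression was measured by RNA sequencing in mouse hematopoietic cells transformed with MLL-AF9, a fusion oncogene of acute myeloid leukemia that was delivered by retrovirus. The starting cells were lineage-negative, which means that cells with surface markers of mature blood lineages had been removed. They came from mice that carried either the normal A20 gene or a floxed A20 gene, together with a Cre recombinase activated by tamoxifen. All cultures received 1 µM 4-hydroxytamoxifen for 48 h. The series held 3 libraries labelled A20 WT and 3 labelled A20 KO, and the question was how deletion of A20 altered the transcriptome of these cells. A20, encoded by Tnfaip3, is a ubiquitin-editing enzyme that restrains NF-κB signalling. The WT-labelled libraries held 25415274, 17095581 and 19125276 counted reads and the KO-labelled libraries 24168326, 22382379 and 16113320. Group means did not differ in depth beyond the spread between libraries (20.5 ± 4.34 against 20.9 ± 4.23 M reads, SD, n = 3; exact two-sided permutation p = 1, where 3 against 3 libraries allow no p below 0.1). More genes had at least 1 read in the KO-labelled libraries (14412 ± 240 against 13850 ± 378, n = 3; exact permutation p = 0.1, the smallest possible). Levels below are means ± SD of TMM-scaled CPM (read counts scaled to library size) over 3 libraries per group.

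Tnfaip3, the targeted gene, was higher in the libraries labelled KO. Its level was 7.39, 8.67 and 8.24 CPM in the WT-labelled libraries and 100.1, 74.1 and 79.1 CPM in the KO-labelled libraries, with group means of 8.10 ± 0.65 and 84.4 ± 13.8. The log2 fold change was 3.38 (SE 0.17; adjusted p = 4.71e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and every KO-labelled library lay above every WT-labelled library. The gene lies on chromosome 10 at 19000910 to 19015657 of mm10, on the minus strand. Counts covered all annotated exons of the gene together, so reads from exons outside the floxed part were included and the total does not measure the deletion. Because the targeted gene went against its label, groups are named here by their labels, and every direction below is KO-labelled relative to WT-labelled.

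**Figure D1:**
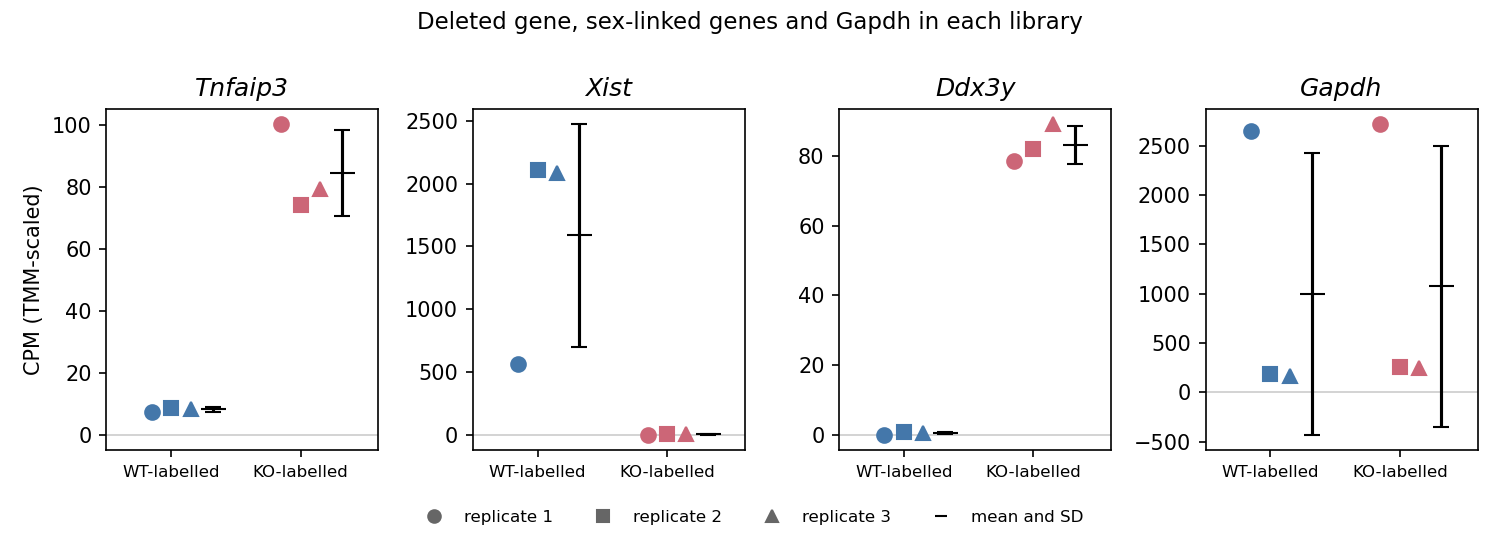
Expression of Tnfaip3, Xist, Ddx3y and Gapdh in each library, in TMM-scaled CPM on linear axes, with a symbol per replicate number and the mean and SD of each group beside the points. Tnfaip3 lay between 7.39 and 8.67 CPM in the WT-labelled libraries and between 74.1 and 100.1 CPM in the KO-labelled libraries; Xist and Ddx3y were found almost exclusively in opposite groups; Gapdh was at 2645 and 2716 CPM in replicate 1 of the groups and between 167 and 254 CPM in replicates 2 and 3.

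The donors of the 2 groups differed in sex by their transcripts. Xist, the RNA that coats the inactive X chromosome in female cells, had 564, 2109 and 2090 CPM in the WT-labelled libraries and 0, 4.76 and 4.77 CPM in the KO-labelled libraries. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty showed the opposite pattern, with Ddx3y at 0.47 ± 0.42 CPM in the WT-labelled and 83.3 ± 5.43 CPM in the KO-labelled libraries. Kdm5d rose from 0.17 to 50.7 CPM and Uty from 0.15 to 37.6 CPM. All 5 of these genes passed the edgeR quasi-likelihood test (largest adjusted p = 0.0044, for Xist). Genes on chromosomes X and Y made up 3.23% of the called genes with a known position and 3.12% of such tested genes (odds ratio 1.05, 95% interval 0.83 to 1.34, Fisher's exact p = 0.67). Genotype label and donor sex therefore changed together in every library.

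Differences between the groups were broad and extended to genes with hardly any reads in the other group. Of 12126 genes tested, 27.3% were called by edgeR's quasi-likelihood test at an adjusted p under 0.05. In the KO-labelled libraries 1660 were higher and 1656 lower. Of these, 988 and 1003 changed at least 2-fold. The share of 27.3% belongs beside list counts from all 6 libraries only. Replicates 2 and 3 alone gave 3149 higher and 3309 lower of 12201 tested genes. The numbers were 2712 and 2568 of 12343 without WT-labelled replicate 1, and 939 and 916 of 12361 without KO-labelled replicate 2. List counts below from such settings go with these larger or smaller shares. Sgce rose from 0 reads in all WT-labelled libraries to 12.1 ± 2.70 CPM, at least 81.1-fold higher against a floor of 3 counts per library. Xlr4b, a lymphocyte-regulated gene on chromosome X, was at least 73.0-fold higher. Lin28a, an RNA-binding protein of early development, had 1 read in the WT-labelled libraries and 1226 in the KO-labelled libraries, a ratio of mean CPM of 1027 (95% counting interval 218 to 48054). Tmc7 rose from 0.044 to 33.2 CPM. In the other direction, Ranbp17 fell from 11.6 ± 1.72 CPM to 0 reads, at least 78.3-fold lower. Kcnk12 and Nrip1 had 1 read each in the KO-labelled libraries against 22.4 and 20.5 CPM in the WT-labelled libraries, ratios of 8.87e-04 (counting interval 1.79e-05 to 0.0039) and 9.71e-04 (1.99e-05 to 0.0044). Hmgn3, a nucleosome-binding protein, fell from 70.8 to 0.089 CPM, and Cd55, which protects cells from complement, fell from 293 ± 56.5 to 0.40 CPM. Hlf, a transcription factor of hematopoietic stem cells, fell from 28.2 to 0.034 CPM. Counting intervals and floors cover counting error only.

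The genes with the smallest p-values changed in either direction. Myl10 fell from 132 ± 10.97 to 0.54 ± 0.11 CPM and Padi4, which citrullinates histones in neutrophils, from 163 ± 20.6 to 1.31 ± 0.20 CPM. Afap1, an actin-binding protein, rose from 3.48 ± 0.21 to 86.1 ± 2.14 CPM. Cd34, a surface marker of hematopoietic progenitors, fell from 613 ± 17.5 to 1.63 ± 0.42 CPM. Their log2 fold changes were −7.93 (SE 0.20), −6.95 (SE 0.20), 4.63 (SE 0.13) and −8.55 (SE 0.26), each with an adjusted p of 1.4e-05 by edgeR. Smoc1 rose by 6.53 (SE 0.22) and the glutamate receptor subunit gene Gria3 fell by 6.97 (SE 0.23) on the log2 scale.

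Among the called genes, 3310 had no overlap between the groups. Over all tested genes 47.6% had none, where chance gives 10% for 3 against 3 independent libraries. Replicates 2 and 3 of each group lay closer to each other than to replicate 1, so chance may give more than 10% here. The number of calls depended on single libraries. It was 2712 higher and 2568 lower without WT-labelled replicate 1, 1098 and 1169 without KO-labelled replicate 1, 939 and 916 without KO-labelled replicate 2, and 987 and 943 without KO-labelled replicate 3. KO-labelled replicates 2 and 3 were much closer to each other (chi-square per degree of freedom 2.43) than to replicate 1 (99.4 and 83.9), and with both summed into 1 sample the counts were 982 higher and 945 lower.

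Replicate 1 stood apart from replicates 2 and 3 in both groups. Gapdh had 2645, 181 and 167 CPM in the WT-labelled libraries and 2716, 254 and 248 CPM in the KO-labelled libraries, and 196 genes were shifted at least 2-fold in the same direction in replicate 1 of both groups, while 225 were shifted in opposite directions. Within replicates 2 and 3 alone, 3149 genes were higher and 3309 lower, whereas replicate 1 had 1 library per group and allowed no test. With replicates 2 and 3 summed into 1 sample in each group, 543 were higher and 518 lower. Under that summing Xist, Irgm2, Mapkapk2, Cdk6, Hoxa9, Stat5a, Csf2ra, Irf5, Cx3cr1, Mrc1, Fcgr1, Bax, Apaf1, Tnip3, H2-Oa, Hsd17b7 and Fdps, each called over all libraries, did not pass (adjusted p from 0.050 for Hsd17b7 to 0.23 for Cdk6). With only KO-labelled replicates 2 and 3 summed, Irgm2, Cdk6, Stat5a, Mrc1 and Fcgr1 did not pass (0.060 to 0.16). The same genes did not pass with a replicate block (edgeR adjusted p from 0.054 for Stat5a to 0.082 for Fcgr1). Across genes, which are not independent replicates, log2 fold changes of the replicate 1 pair and of replicates 2 and 3 correlated at 0.76. Principal component 1 (75.9% of the variance) separated the groups, component 2 (14.8%) set WT-labelled replicate 1 apart and component 3 (5.65%) KO-labelled replicate 1. Nothing in the labels says that replicates came from separate cultures or animals, so p-values measure the spread between these libraries, which may be technical.

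**Figure D2:**
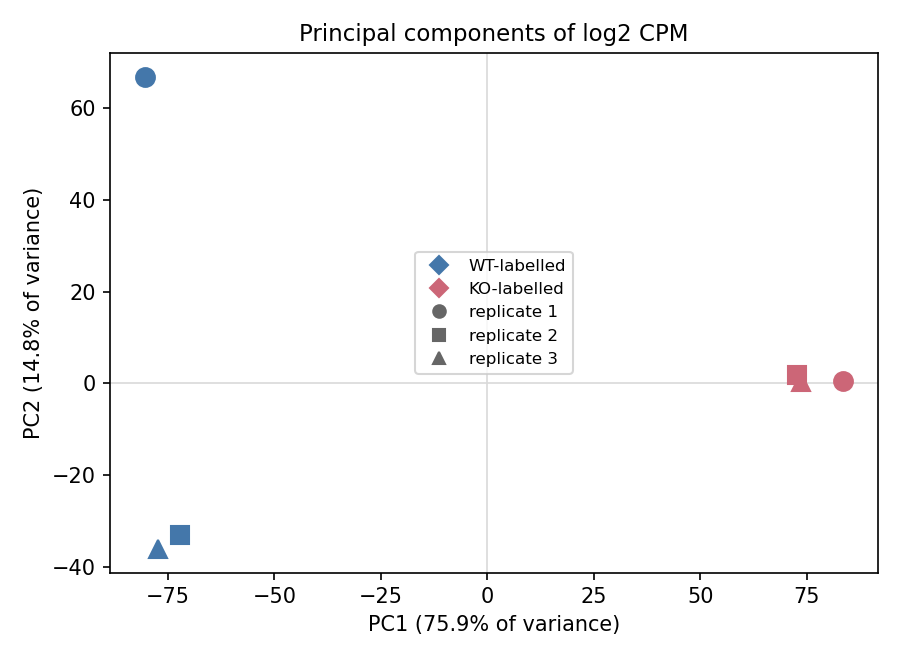
Principal components 1 and 2 of log2 CPM for the 6 libraries, with color for the label and shape for the replicate number; each axis gives its share of the variance. Component 1 (75.9%) separated WT-labelled from KO-labelled libraries, and component 2 (14.8%) set replicate 1 of the WT-labelled group apart from the other 5 libraries.

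Genes that NF-κB induces as feedback and survival factors were called higher more often than lower in the KO-labelled libraries, the group with higher Tnfaip3. Of 27 tested members, 13 rose, 1 fell and 13 did not pass; adjusted over the list alone, 14 rose and 1 fell. Nfkbia, the inhibitor that retains NF-κB in the cytoplasm, rose from 39.7 ± 10.3 to 202 ± 8.60 CPM. Its companions included Tnip1, a partner protein of A20 (log2 fold change 1.43, SE 0.13), the NF-κB subunit gene Nfkb2 (2.36, SE 0.26) and the adhesion molecule Icam1 (3.02, SE 0.34), with adjusted p between 4.2e-04 and 0.0011 by edgeR. Stat5a, the member that fell, was named after its value was seen and is a cytokine-activated transcription factor (52.7 to 33.1 CPM). Its call was lost when any KO-labelled library was left out (adjusted p = 0.050, 0.060 and 0.060 without replicates 1, 2 and 3). The list's median log2 fold change was 1.19 (camera adjusted p = 1.46e-05 over 29 lists). With an estimated correlation camera gave an adjusted p of 0.38, the upper end of the range over 18 camera alternatives (5.72e-07 to 0.38). That setting passed 0 of the 29 lists, so here and below it tells no list from another. In replicates 2 and 3 alone 16 members were higher and 4 lower, and without WT-labelled replicate 1 16 and 3.

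Inflammatory cytokines and chemokines showed the largest list median, 2.22 on the log2 scale, of the 8 primary lists. Of 20 tested members 12 rose and 0 fell, and the counts were the same adjusted over the list alone. Tnf rose from 7.47 ± 1.15 to 85.2 ± 4.47 CPM, Cxcl10 from 1.02 to 18.8 CPM, the macrophage growth factor gene Csf1 from 26.3 ± 12.5 to 192 ± 2.95 CPM, and Ccl5 from 0.16 to 7.004 CPM. Their adjusted p ranged from 3.04e-05 to 0.0020 by edgeR, and camera gave an adjusted p of 1.13e-05 for the list (adjusted p = 0.47 with an estimated correlation; range over 18 camera alternatives 5.59e-07 to 0.47). The number of members that rose was 7 when any 1 of the 3 KO-labelled libraries was left out, and 12 with 4 lower in replicates 2 and 3 alone.

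Interferon-stimulated genes did not move together. Of 44 tested members 4 were higher and 6 lower, with the same counts adjusted over the list alone, and the list median was −0.06 (camera adjusted p = 0.85). Ifi47, an interferon-induced GTPase, fell from 31.2 ± 4.21 to 8.56 ± 0.55 CPM, Ddx60 from 7.42 ± 4.72 to 0.20 ± 0.14 CPM and Irgm2 from 22.7 to 10.8 CPM, while Samd9l rose from 16.8 to 34.8 CPM (adjusted p 3.5e-04 to 0.016 by edgeR). Irgm2 lost its call without KO-labelled replicate 2 or 3 (adjusted p = 0.071 and 0.068). In replicates 2 and 3 alone 6 were higher and 23 lower, and without WT-labelled replicate 1 5 and 18. Counts were 2 and 3 without WT-labelled replicate 2 or KO-labelled replicate 1, 1 and 3 without WT-labelled replicate 3, 1 and 2 without KO-labelled replicate 2, and 2 and 2 without KO-labelled replicate 3.

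Genes of necroptosis and of the TNF receptor complex went both ways. Of 32 tested members 8 rose and 5 fell, also when adjusted over the list alone, and the list median was 0.06 (camera adjusted p = 0.43). Mlkl, the executioner of necroptosis, fell from 87.7 ± 18.6 to 23.2 ± 0.69 CPM. Birc3, a ubiquitin ligase of the receptor complex, rose from 28.5 to 101 CPM, the death receptor gene Fas from 2.28 ± 1.15 to 21.5 ± 0.96 CPM and the kinase gene Mapkapk2 from 425 ± 23.3 to 932 ± 47.8 CPM, with adjusted p of 3.9e-04 to 0.0017 for the 4 genes by edgeR. Counts were 11 higher and 10 lower in replicates 2 and 3 alone, 10 and 8 without WT-labelled replicate 1, 5 and 4 without WT-labelled replicate 2 or KO-labelled replicate 1, 5 and 5 without WT-labelled replicate 3, and 4 and 1 without KO-labelled replicate 2 or 3.

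Genes of the MLL-AF9 leukemia program went both ways. Of 25 tested members 4 rose and 10 fell, the same as adjusted over the list alone. Besides Cd34, the cytokine receptor gene Flt3 fell from 21.2 ± 1.91 to 0.84 ± 0.12 CPM, the transcription factor gene Sox4 from 95.2 ± 6.17 to 17.8 ± 1.22 CPM and the survival gene Bcl2 from 118 ± 8.45 to 27.3 ± 1.85 CPM, with adjusted p of 4.0e-05 to 8.3e-05 by edgeR. Members that rose, named after their values were seen, included Hoxa10 (123 to 337 CPM), Hoxa9 (143 to 253 CPM) and Cdk6 (86.3 to 118 CPM). The Cdk6 call (adjusted p = 0.045) was lost without any library except WT-labelled replicate 1, with adjusted p from 0.052 without KO-labelled replicate 1 to 0.16 without KO-labelled replicate 3. It was also lost with upper-quartile scaling (0.063), library totals (0.12) or no low-count filter (0.054). The median of the list was −0.07 and its mean −1.06, and camera placed it lower (adjusted p = 7.24e-05; adjusted p = 0.21 with an estimated correlation and 0.090 with limma-voom; range over 18 camera alternatives 3.95e-06 to 0.21).

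Markers of monocyte and macrophage maturation included 10 members that rose and 3 that fell of 31 tested; adjusted over the list alone, 12 rose and 3 fell. The pattern receptor gene Tlr2 rose from 35.9 ± 12.5 to 271 ± 67.5 CPM, its co-receptor Cd14 from 25.0 ± 14.0 to 361 ± 137 CPM, the cytokine receptor gene Csf2ra from 25.9 to 139 CPM and the transcription factor gene Irf5 from 18.9 to 52.4 CPM (adjusted p 9.5e-04 to 0.0084 by edgeR). The 3 that fell were named after their values were seen: Cx3cr1 (11.2 to 3.68 CPM), a chemokine receptor, Mrc1 (16.1 to 0.24 CPM), the mannose receptor, and Fcgr1 (10.0 to 2.28 CPM), an antibody receptor. Mrc1 lost its call with limma-voom (adjusted p = 0.24) and without KO-labelled replicate 2 or 3 (0.067 and 0.061), and Fcgr1 with limma-voom (0.060), without WT-labelled replicate 2 or 3 (0.061 and 0.058) or KO-labelled replicate 2 or 3 (0.067 and 0.065). The list median was 0.57 (camera adjusted p = 0.027; adjusted p = 0.69 with an estimated correlation). The camera call was lost without WT-labelled replicate 1 (adjusted p = 0.42), without KO-labelled replicate 1 (0.075), with a term for replicate 1 (0.052) and in replicates 2 and 3 alone (0.29), where 14 members were higher and 13 lower; over 18 camera alternatives the adjusted p ranged from 0.0011 to 0.69. Counts were 12 and 7 without WT-labelled replicate 1, 6 and 3 without KO-labelled replicate 1, and 6 and 2 without WT-labelled replicate 3 or KO-labelled replicate 2 or 3.

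Neutrophil genes and primary granule genes were mixed, with some of the largest falls of the comparison. Among 17 tested genes of neutrophil maturation and secondary granules 4 rose and 7 fell (4 and 8 adjusted over the list alone). Padi4 and the antibacterial protein gene Pglyrp1 fell, the latter from 97.3 ± 8.42 to 5.15 ± 0.76 CPM, whereas Olfm4 rose from 0.080 to 9.82 CPM and Mcemp1 from 2.28 ± 1.63 to 84.1 ± 10.5 CPM. The median was −0.45 (camera adjusted p = 0.11), and the number that fell was 4 without WT-labelled replicate 2 or 3 or KO-labelled replicate 1, 3 without KO-labelled replicate 2 or 3, and 9 in replicates 2 and 3 alone, where the list passed camera (adjusted p = 8.74e-04; range over 18 camera alternatives 8.74e-04 to 0.63). Among 17 genes of primary granules and granulocyte-monocyte progenitors 4 rose and 7 fell (4 and 10 adjusted over the list alone). Mpo, the myeloperoxidase of primary granules, fell from 200.05 ± 86.2 to 0.43 ± 0.21 CPM, Nkg7 from 29.9 ± 2.81 to 0.21 ± 0.05 CPM and the protease gene Prss57 from 41.0 to 1.03 CPM, while the protease inhibitor gene Cst7 rose from 2.00 to 73.1 CPM (adjusted p 2.4e-05 to 1.7e-04 by edgeR). The median was −0.80 (camera adjusted p = 0.040; adjusted p = 0.38 with an estimated correlation). That call was lost without KO-labelled replicate 1 (adjusted p = 0.074), with library totals (0.053), limma-voom (0.097) or a term for replicate 1 (0.099), and in replicates 2 and 3 alone (0.080), where 4 members were higher and 10 lower; over 18 camera alternatives it ranged from 0.017 to 0.38.

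**Figure D3:**
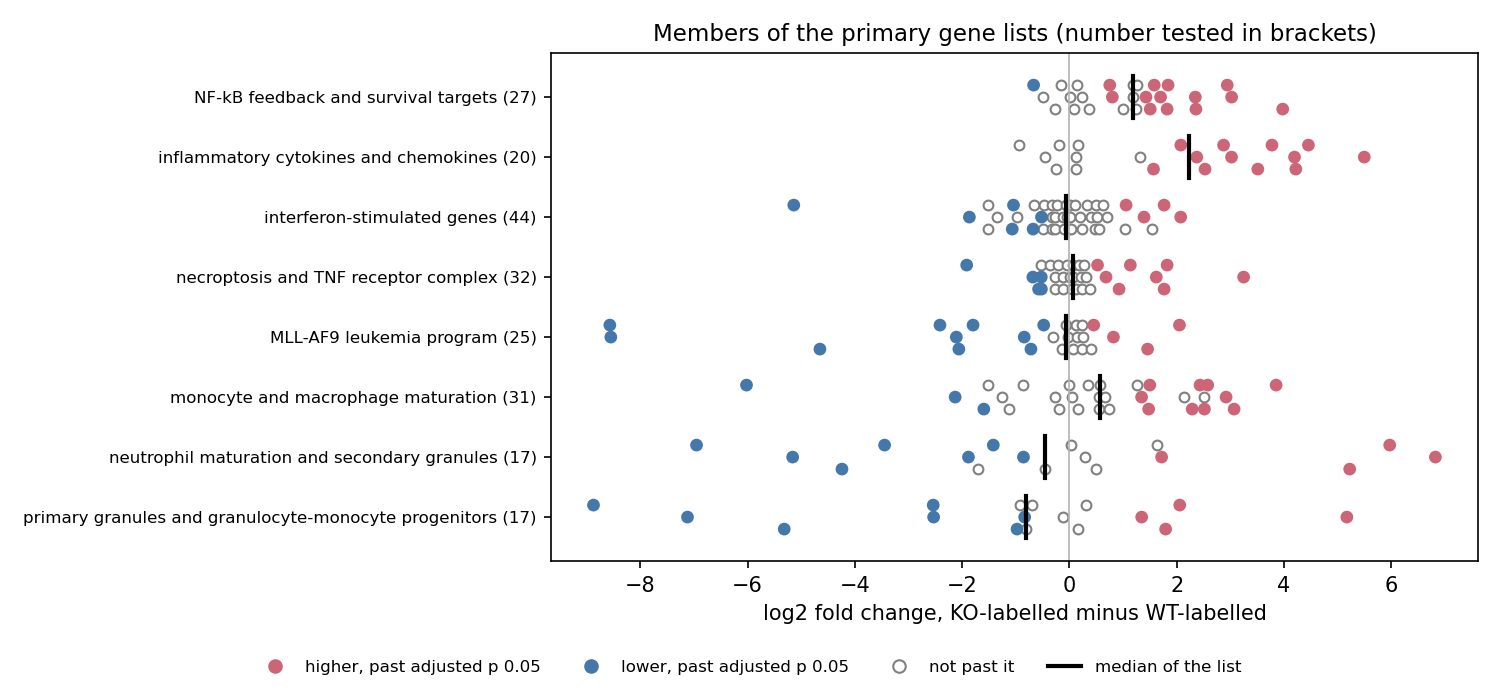
Log2 fold changes, KO-labelled minus WT-labelled, of each tested member of the 8 primary gene lists; filled points passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, open points did not, and black bars mark list medians. NF-κB targets (median 1.19) and inflammatory cytokines (2.22) lay mostly above 0, while interferon-stimulated genes (−0.06) were centred near it.

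Of 26 tested targets of p53, 13 rose, 1 fell and 12 did not pass (15 and 1 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 2.81e-05; adjusted p = 0.19 with an estimated correlation). Plk2 rose from 0.14 ± 0.03 to 13.1 ± 0.59 CPM, the cell-cycle inhibitor gene Cdkn1a from 89.0 ± 10.5 to 291 ± 27.6 CPM and Mdm2, the ligase that degrades p53, from 64.9 to 123 CPM (adjusted p up to 0.0014 by edgeR). Of 22 cholesterol synthesis genes 9 rose, 0 fell and 13 did not pass (10 and 0 adjusted over the list alone; median 0.43, camera adjusted p = 0.0092, adjusted p = 0.63 with an estimated correlation). Examples were Hsd17b7 (19.96 to 50.8 CPM), Fdps (259 to 543 CPM) and Mvd (46.8 to 98.0 CPM). The cholesterol count was 5 without WT-labelled replicate 2 or KO-labelled replicate 2 or 3, and in replicates 2 and 3 alone it was 19, beside 19 higher and 3 lower p53 targets.

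Several lists did not pass camera. Apoptosis regulators of the BCL2 family had 6 higher and 3 lower of 19 (7 and 3 adjusted over the list alone; camera adjusted p = 0.48), with Bax (155 to 312 CPM) and Apaf1 (71.0 to 144 CPM) higher beside lower Bcl2. Inflammasome and pyroptosis genes had 5 higher and 0 lower of 15 (6 and 0 over the list alone; 0.066), led by Nlrc4 (3.09 to 50.6 CPM). Among 22 partners of A20 and ubiquitin-editing genes 6 rose and 2 fell (7 and 2 over the list alone; 0.15): Tax1bp1, an adaptor of A20, fell from 1098 ± 120 to 391 ± 4.25 CPM, and Irak2 and Tnip3 rose from 15.0 to 81.2 and from 5.35 to 117 CPM. MHC class I and immunoproteasome genes had 1 higher and 6 lower of 16 (the same over the list alone; 0.17), and MHC class II genes 5 higher and 2 lower of 12 (the same over the list alone; 0.062), with H2-DMb1 and Cd80 higher and H2-Oa lower. Integrated stress and unfolded protein response genes had 5 higher and 0 lower of 27 (the same over the list alone; 0.34); their median was −0.02 and their mean 0.30. Glycolysis and hypoxia genes had 7 higher and 1 lower of 27 (7 and 2 over the list alone; 0.076).

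Leaving out a library moved several of these counts. Without WT-labelled replicate 2, KO-labelled replicate 2 or KO-labelled replicate 3 stress response genes had 3 higher and glycolysis genes 3 higher, and without WT-labelled replicate 3 stress response and inflammasome genes had 3 higher each. Glycolysis genes had 4 higher without KO-labelled replicate 1. The MHC class I count of lower genes was 2 without KO-labelled replicate 2 and 1 without KO-labelled replicate 3. MHC class II passed camera without WT-labelled replicate 2 (adjusted p = 0.015), KO-labelled replicate 2 (0.022) or KO-labelled replicate 3 (0.022), and inflammasome genes without WT-labelled replicate 2 (0.026), WT-labelled replicate 3 (0.0498) or KO-labelled replicate 3 (0.0499); ranges over 18 camera alternatives were 0.0098 to 0.63 and 0.026 to 0.63. In replicates 2 and 3 alone MHC class I genes passed camera (adjusted p = 0.011, range over 18 camera alternatives 0.011 to 0.63), with 2 higher and 10 lower. So did glycolysis genes (0.020, range 0.020 to 0.38). The glycolysis list also passed with limma-voom (0.028), a replicate block (0.035), a term for replicate 1 (0.041) and without a low-count filter (0.0496). MHC class II and inflammasome genes passed without that filter (0.046 each) and with replicates 2 and 3 summed in each group (0.0098 and 0.029), and MHC class II also with those of the KO-labelled group alone summed (0.022).

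Lists of proliferation and energy metabolism held few calls over all libraries. S phase genes had 1 higher and 2 lower of 29 (0 and 2 adjusted over the list alone; median −0.51, camera adjusted p = 0.066), and G2/M genes 0 higher and 2 lower of 28 (0 and 0 over the list alone; median −0.41, 0.061). Of G2/M genes 0 were lower without WT-labelled replicate 3 and 1 without KO-labelled replicate 2 or 3; of S phase genes 1 was lower without KO-labelled replicate 2 or 3, and 0 were higher without any library except WT-labelled replicate 1, which gave 2. In replicates 2 and 3 alone S phase genes had 6 higher and 6 lower, and G2/M genes 0 higher and 8 lower. Both lists passed camera without WT-labelled replicate 2 or 3 or KO-labelled replicate 2 or 3. In that order adjusted p was 0.015, 0.023, 0.028 and 0.033 for S phase and 0.015, 0.038, 0.012 and 0.016 for G2/M genes. With all libraries kept both passed with limma-voom (0.0093 and 0.0027), without a low-count filter (0.030 and 0.022), with replicates 2 and 3 summed in the KO-labelled group (0.031 and 0.015) and in each group (0.0077 and 0.0070); over 18 camera alternatives they ranged from 0.0077 to 0.86 and from 0.0027 to 0.71. Oxidative phosphorylation had 1 higher of 30 by edgeR (0 over the list alone, camera adjusted p = 0.31). Ribosome biogenesis had 0 of 25 (0 over the list alone, 0.89), where 27.3% of all tested genes were called. The ribosome biogenesis count rose to 18 higher in replicates 2 and 3 alone and to 10 without WT-labelled replicate 1. That of oxidative phosphorylation rose to 15 and 11, and was 0 without WT-labelled replicate 3 or any KO-labelled library. Without WT-labelled replicate 1 inflammasome genes had 7 higher and 4 lower, stress response genes 9 and 4 and glycolysis genes 10 and 3; in replicates 2 and 3 alone the counts were 7 and 5, 12 and 6, and 14 and 3.

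Of 5 lists with markers of other cell types that such cultures can hold, those of mast cells and basophils and of dendritic cells and eosinophils passed camera. Only part of the listed symbols were tested: 8 of 17 for mast cells, 5 of 18 for dendritic cells and 6 of 16 for stromal cells. Whether the share of such cells differed between the groups was not tested. Mast cell and basophil markers had 0 higher and 4 lower of 8 (the same adjusted over the list alone; median −1.87, camera adjusted p = 0.0037, adjusted p = 0.22 with an estimated correlation), among them Kit (353 to 102 CPM), which the MLL-AF9 list also holds, and Gata2 (79.6 ± 34.8 to 4.93 ± 0.19 CPM). Dendritic cell and eosinophil markers had 0 higher and 2 lower of 5 (the same over the list alone; median −2.19, 0.0037, and 0.38 with an estimated correlation), namely Flt3, shared with the MLL-AF9 list, and Tcf4 (78.7 to 11.98 CPM). The latter list lost its camera call without KO-labelled replicate 1 (adjusted p = 0.065) and without a low-count filter (0.14; range over 18 camera alternatives 0.0038 to 0.38). Erythroid and megakaryocyte markers had 1 higher and 4 lower of 8 (the same over the list alone; 0.062), with Itga2b at 26.6 and 0.83 CPM; 2 were lower without WT-labelled replicate 2 or 3 or KO-labelled replicate 1 or 2, 0 were higher without WT-labelled replicate 2 or KO-labelled replicate 1, and camera called the list without KO-labelled replicate 3 (adjusted p = 0.047), without a low-count filter (0.030) and with KO-labelled replicates 2 and 3 summed (0.041; range over 18 camera alternatives 0.030 to 0.38). Lymphoid markers had 1 higher and 3 lower of 5 (the same over the list alone; 0.17), with Gzmb at least 12.4-fold lower; 1 was lower without KO-labelled replicate 2, and 0 were higher without WT-labelled replicate 2 or 3 or KO-labelled replicate 1. Stromal and endothelial markers had 2 higher and 2 lower of 6 (the same over the list alone; 0.47), with Thy1 falling from 460 ± 194 to 5.47 ± 0.71 CPM; that list passed camera in replicates 2 and 3 alone (adjusted p = 0.0040; range over 18 camera alternatives 0.0040 to 0.73). Immediate early genes had 5 higher and 1 lower of 19 (6 and 1 over the list alone; 0.062), among them Junb (45.5 to 114 CPM) and Egr3, with Dusp2 lower. They passed camera without WT-labelled replicate 2 (adjusted p = 0.015), WT-labelled replicate 3 (0.030) or KO-labelled replicate 3 (0.047), with limma-voom (0.018), without a low-count filter (0.030) and with replicates 2 and 3 summed in the KO-labelled group (0.049) or in each group (0.020), within a range of 0.015 to 0.63 over 18 camera alternatives, and had 9 higher and 4 lower without WT-labelled replicate 1, 3 and 1 without KO-labelled replicate 1, and 2 and 1 without KO-labelled replicate 2 or 3. Replication-dependent histones, which poly(A) selection captures poorly, had 0 higher and 8 lower of 16 (0 and 9 over the list alone; median −1.99, camera adjusted p = 0.033, adjusted p = 0.63 with an estimated correlation). The histone count fell to 0 without KO-labelled replicate 3 and to 1 without KO-labelled replicate 1 or 2. It fell to 2 and 5 without WT-labelled replicates 2 and 3, and rose to 13 without WT-labelled replicate 1. Rn45s took 1.99 and 2.92% of counts in WT-labelled replicates 2 and 3, against 0.22% in WT-labelled replicate 1 and 0.32 to 0.41% in the KO-labelled libraries. Whether poly(A) selection differed between libraries was not tested, so the histone difference may not belong to the label. The camera call was lost without WT-labelled replicate 2 (adjusted p = 0.060) and with a stricter low-count filter (0.13, range over 18 camera alternatives 0.0038 to 0.63).

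Some named genes share sequence with other genes, and their counts are uncertain. The share of 31-mers found in transcripts of other genes was 57.8% for Xlr4b, 52.3% for Sox4, 51.5% for H2-Q4, 38.8% for Prss57, 31.6% for H2-DMb1, 30.1% for Npm1 and 29.3% for Fdps; it was 0 for Tnfaip3 and 31.3% for Gapdh.

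Calls were more frequent near the targeted gene. Within 20 Mb of Tnfaip3 on chromosome 10, 35 of 93 tested genes were called (37.6%) against 27.5% elsewhere (odds ratio 1.59, 95% interval 1.01 to 2.47, two-sided Fisher's exact p = 0.035). Within 5 Mb the count was 19 of 32 (odds ratio 3.86, 1.80 to 8.51, Fisher's exact p = 1.89e-04), and over the whole chromosome it was 161 of 555 (odds ratio 1.08, Fisher's exact p = 0.44). Among these neighbours, named after their values were seen, Reps1 fell from 114 ± 10.1 to 43.7 ± 4.50 CPM, Map7 from 39.4 ± 11.5 to 5.81 ± 0.65 CPM and Perp, a p53 target, from 3.39 ± 2.39 to 0.035 ± 0.031 CPM.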

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

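The alternatives with a term for replicate 1, with replicates 2 and 3 alone, with summed replicates and without Rn45s or multi-copy genes were chosen only after the data were seen, as were the alternatives of 21 genes. Of 24 alternatives, 14 kept the number of higher genes within 1.5 times 1660 and 15 the number of lower genes within 1.5 times 1656; 0 called genes changed sign in any. Counts moved to 989 higher and 1034 lower with a replicate block, 821 and 873 at an adjusted p under 0.01, 914 and 951 when tested against a log2 change of 0.5, 3149 and 3309 in replicates 2 and 3 alone, 982 and 945 with KO-labelled replicates 2 and 3 summed, and 543 and 518 with both groups' replicates 2 and 3 summed. Leaving out 1 library gave 939 to 2712 higher and 916 to 2568 lower. Deviations of same-numbered replicates correlated over all genes at −0.01, −0.06 and 0.05, below the 0.1 set for a pairing, although those of replicate 1 correlated at 0.48 over 1480 multi-copy genes. With an estimated correlation adjusted p was 0.38 for NF-κB targets, 0.47 for cytokines, 0.21 for the MLL-AF9 list, 0.69 for monocyte genes and 0.38 for primary granule genes. By fry it was 0.020 for necroptosis genes and 0.19 for monocyte genes. Fry's mixed test gave an adjusted p of 4.92e-05 for interferon-stimulated, 3.78e-05 for necroptosis and 5.90e-06 for neutrophil genes. That test passed 25 of the 29 lists, so it hardly tells 1 list from another. With limma-voom camera's adjusted p was 0.090 for the MLL-AF9 list and 0.097 for primary granules. Primary granule genes had 0.053 with library totals, 0.080 with a replicate block, 0.099 with a term for replicate 1 and 0.080 in replicates 2 and 3 alone; monocyte genes had 0.052 and 0.29 in the last pair, and neutrophil genes 8.74e-04 in replicates 2 and 3 alone. Leaving out 1 library gave 0.0032 to 0.42 for monocyte and 0.022 to 0.074 for primary granule genes. In replicates 2 and 3 alone Npm1 (0.13) and Ncl (0.40) reversed on the log2 scale, with −0.52 to 0.061 and −0.42 to 0.25 when 1 library was left out, and ribosome biogenesis reversed (adjusted p = 0.011). Over 149 named genes, 2503 of 2676 alternatives kept the direction and the side of the threshold, 169 lost the call and 4 reversed. For these changes the cause was not tested. In simulated independent libraries with 100 genes changed 2-fold and 100 changed 4-fold, edgeR recovered 34% and 85% of them. It made 123 calls there against 3316 in the data, so these are not the recovery rates of this contrast. A gene without a call may still differ.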

Other observations

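Tests of a single mislabelled library, of exchanged labels and of a batch shared by the replicate 1 libraries were chosen only after the result was seen, and the genes described first, except Xist, Ddx3y and Sgce, were chosen after their values were seen. Directions are KO-labelled relative to WT-labelled, with Tnfaip3 higher in the KO-labelled group. Erg, a transcription factor of hematopoietic stem cells, fell from 83.8 ± 6.52 to 0.20 ± 0.17 CPM (log2 fold change −8.71; adjusted p = 7.83e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, n = 3). Aff3 fell from 52.7 to 0.15 CPM, the chromatin protein gene Hmga2 from 31.9 to 0.19 CPM and the adhesion receptor gene Gpr56 from 355 ± 185 to 8.81 ± 0.46 CPM. Zbtb16 fell from 61.9 to 9.80 CPM.

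Irg1, which makes itaconate in activated macrophages, rose from 0.44 ± 0.35 to 86.5 ± 7.51 CPM (log2 fold change 7.68; adjusted p = 1.43e-04 by edgeR). The adhesion molecule gene Vcam1 rose from 0.17 to 42.7 CPM, Thbs1 from 41.8 ± 3.76 to 418 ± 34.5 CPM and Hpgd, which degrades prostaglandins, from 80.7 ± 23.01 to 1606 ± 176 CPM. The imprinted genes Peg10, which lies on chromosome 6 as Sgce does, and Peg13 went apart, from 0.066 to 19.1 CPM and from 65.4 to 12.2 CPM. KO-labelled replicates 2 and 3 held 110 and 80 Xist reads and WT-labelled replicates 2 and 3 held 14 and 12 Ddx3y reads, while replicate 1 of either group held 0. Rn45s took 0.22, 1.99 and 2.92% of counts in the WT-labelled and 0.39, 0.32 and 0.41% in the KO-labelled libraries (exact permutation p = 0.4).

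Tnfaip3 was higher in the libraries labelled KO. A single mislabelled library is argued against, since the lowest KO-labelled level was 8.54 times the highest WT-labelled level, and so are reads from other gene copies, since 0% of its 31-mers occur in other genes. Exchanged group labels and induced transcription of a gene that keeps most exons cannot be told apart here. The NF-κB list had a median log2 fold change of 1.19, but Tnfaip3 is itself induced by NF-κB and the donors also differed between the groups, so this value does not decide. Both may account for the pattern, and exon-level reads were not used here.

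Donor sex changed with the label. Tested genes on chromosomes X and Y numbered 356 and 4, against 3184 called genes with a position. Genes on these chromosomes could therefore not have made up most calls, whatever the effect of sex. Their share of 3.23% does not measure how much donor sex added to the calls. Passenger variants linked to the floxed gene may account for some calls near it, with an odds ratio of 1.59 (95% interval 1.01 to 2.47), but the window holds 35 of 3316 calls. Sex effects on autosomal genes, and differences between donors or between independently transformed cultures, stay open as untested, since each changed with the label.

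Replicate 1 stood apart in both groups. Of 196 genes shifted at least 2-fold alike in both groups, 182 had 31-mers. Of these, 59.9% had at least 20% of their 31-mers in other genes, against 12.1% of other genes (odds ratio 10.9, 95% interval 7.97 to 14.9). A different counting in replicate 1 of reads that several genes share is therefore a candidate explanation for part of these genes. The measure does not separate gene copies from overlapping genes, such as Snord2 and Snord57 (100% shared each). Over 7647 genes with few shared 31-mers the deviations of both groups correlated at −0.28, so these genes did not move alike as a set. The correlation cannot exclude a shared batch. Effects of single libraries can mask a batch, and a batch may act on part of these genes. Some moved alike, such as Snord49b (0% shared, log2 shift −1.62 in the WT-labelled and −1.60 in the KO-labelled group) and Hist1h1b (4.15%, −2.28 and −2.72). Over all tested genes, 225 were shifted in opposite directions. Replicate 1 of both groups also shared a lack of other-sex reads. KO-labelled libraries held 0, 110 and 80 Xist reads and WT-labelled libraries 0, 14 and 12 Ddx3y reads. Genes are not independent replicates, and what set replicate 1 of each group apart in its other genes stays open.

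Among the 10 splits of the 6 libraries into 3 and 3, the real split called 3316 genes and the highest of the others 0. So 1 split reached the real count, and 10 splits are too few for a share under 0.05. Each other split mixed the groups that principal component 1 (75.9% of the variance) separated, which raises the spread within its sides. Their 0 calls therefore do not tell genotype from any other difference between the groups.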
